A study of Zea mays subsp. mays with 2 samples.

How the data were processed

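RNA from maize endosperm, the starch- and protein-storing tissue of the kernel, was sequenced from wild-type plants and from the dek2 mutant at 15 days after pollination. Per the labels' protocols, RNA was extracted with Trizol, cleaned up with DNase I treatment and made into standard Illumina libraries. Each genotype had 1 sample and 1 deposited table. The design text of the series speaks of triplicates, but no label or header says whether a table is 1 library, a pool or a mean of replicates. Each genotype therefore had n = 1, and no spread between replicates could be computed. The source label reads kernel and the tissue label endosperm. The differences given here compare 2 deposited libraries, have no replicate check, and carry no p-value.

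The deposited values are FPKM, a fragment number scaled for transcript length and for the mapped total, per the file headers. The authors deposited 1 FPKM value per row, and each row is identified by a chromosome, start and end. Per the submitters' processing notes, Bowtie 0.12.2 was used. The program that computed FPKM, the genome build and the annotation are not given in the sources used here. Both tables listed the same 45157 rows in the same order, so that rows were paired between libraries line by line. The rows had 40123 distinct coordinates, and 9637 rows shared their coordinate with at least 1 other row, as happens where several gene models are reported under 1 locus. For these rows the pairing assumes that the gene models of a coordinate stand in the same order in both tables, which could not be checked. No row held an exact 0. The value 1e-05 stood in 6118 rows of wild type and 3690 rows of dek2, in no row in both. The sources used here do not explain it. It was taken as a placeholder and is described as "no value", because a failed estimate and an absent transcript would look alike in it. Other values under 0.001 FPKM stood in 24 rows of wild type and 26 rows of dek2 and were kept as deposited.

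The tables hold no gene identifier or symbol. The reference gene table at hand is for the assembly Zm-B73-REFERENCE-NAM-5.0, and 0 of the row starts equalled a gene start in it. The last coordinate of chromosome 1 was 301363304 in the deposited tables and 308332590 in the reference table. The builds were therefore taken as different, no coordinate was converted, and no locus was given a gene name. The 24 gene lists fixed before the data were examined (storage proteins, starch enzymes, alternative oxidases, respiratory complexes, tissue markers and others) could not be filled and have no values here. The same holds for the transcript of the dek2 gene itself, so the labels could not be checked against it. The rule for naming loci, also fixed before the data were examined, asked for the 10 largest changes in each direction among loci with a name or description, and selected none. In its place, positions are given for the 2 highest and the 2 lowest ratios among rows on chromosomes 1 to 10 with a span of 300 bp or more, 10 FPKM or more in a library, a value in both libraries and a coordinate of their own. This rule, the clusters, the summary of organellar rows and the other loci described by level were chosen after the values were seen. Coordinates are printed as deposited, and whether starts count from 0 or 1 is not given in the sources used here. A span is end minus start and includes introns.

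Absolute sequencing depth is unknown, because FPKM divides it out. Relative depth was read from low values. Among 2807 rows with their own coordinate and values between 0.0001 and 0.3 FPKM in both libraries, the log2 ratio of dek2 to wild type had its main peak at -0.10 (bins of 0.05) and further peaks at 0.90 and -1.10, a spacing of 1 that steps of whole fragments give. The median of the ratios within 0.25 of the main peak was -0.08. A fragment was thus worth slightly less FPKM in dek2, which puts its mapped total at 1.06 times that of wild type. No counting interval per locus could be computed, because transcript lengths were not used here. At 1000 FPKM or more in dek2, 10 of 26 rows with a span under 300 bp had no value in wild type, against 4 of 69 longer rows. Very short loci reach high FPKM from few fragments, and 903 rows had a span under 300 bp.

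The main value of a row was log2((dek2 + 1)/(WT + 1)) with a pseudocount of 1 FPKM, after the dek2 values were divided by the median ratio of the libraries. This median was taken over the 22250 rows at 1 FPKM or more in both. It was 0.59 on the log2 scale, or 1.50-fold. All changes are relative to this shift. The pseudocount understates the change of low loci. A row was counted as higher or lower when it reached 1 FPKM in at least 1 library and differed at least 2-fold, a rule of size and not a test. Abundance classes used the mean of both scaled libraries. Clusters were defined after seeing the data as 3 or more distinct coordinates on 1 chromosome, each at 50 FPKM or more in wild type, 300 bp or more in span and at least 32-fold lower in dek2, with gaps of at most 1 Mb. They were set against 1000 random draws of as many rows from those at 50 FPKM or more in wild type.

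The scaling and counting were tested on simulated data of 45157 rows with a true shift of 0.5. The shift was found as 0.50, and 50 of 50 rows were recovered at each of 4-fold and 32-fold, up and down. Of 26002 unchanged rows, 0 were counted, but the simulated spread between libraries (SD 0.15 on the log2 scale) was far below that in the data. The test therefore checks the computation only and says nothing of how many unchanged rows the 2-fold rule counts with 1 library per genotype. The median of the simulated log2 changes of -5 came out as -4.08, which shows the effect of the pseudocount. Alternatives covered the scaling, the pseudocount, the filter, the fold threshold and the rows used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.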

Results

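The transcriptome of dek2 endosperm was compared with that of wild type at 15 days after pollination, with 1 deposited library per genotype. The dek mutants of maize are named for their defective kernels, and published work describes Dek2 as a pentatricopeptide repeat protein that acts in the splicing of a mitochondrial transcript. The comparison asks which transcripts differ in the mutant endosperm. Expression was given as FPKM for 45157 rows, of which 44983 lay on chromosomes 1 to 10, 130 on unplaced scaffolds, 38 on the mitochondrial and 6 on the plastid genome. FPKM summed to 1139650 in wild type and 1073590 in dek2. At least 1 FPKM was reached by 24237 rows in wild type and by 26489 rows in dek2, and no value was given for 6118 rows in wild type and for 3690 rows in dek2. The deposited tables pair no row with a gene name and the genome build is not given in the sources used here, so loci are identified by position only. With n = 1 per genotype, every difference below is between these 2 libraries and has no replicate error.

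The wild-type endosperm library was dominated by a few loci, and these were much lower in dek2. The 10 most abundant rows held 33.8% of the wild-type FPKM and the 100 most abundant held 53.6%. In dek2 the corresponding shares were 10.8% and 25.2%. The number of rows that made up 50% of the total was 65 in wild type and 726 in dek2. All 10 of the most abundant wild-type rows were more than 8-fold lower in dek2, with log2 ratios from -9.71 to -3.58. None of them was among the 10 most abundant rows of dek2, and 33 of the 100 most abundant rows were shared between the libraries. Of the 100 most abundant wild-type rows, 75 were at least 2-fold lower in dek2 and 3 were at least 2-fold higher. Of the 100 most abundant dek2 rows, 50 were higher in dek2 and 8 were lower. Of the 10 most abundant dek2 rows, 0 were at least 2-fold lower in dek2, and the log2 ratios lay between -0.54 and 13.36. Several of them, that with the highest ratio included, had no value in wild type. The most abundant had a value in both, with 27440 FPKM in dek2 and 4363 FPKM in wild type (log2 ratio 2.07). A span under 300 bp was found in 4 of these 10, against 0 of the 10 most abundant wild-type rows. Rows chosen on one library's level tend to be lower in the other, so the sets from both libraries are given together.

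**Figure D1:**
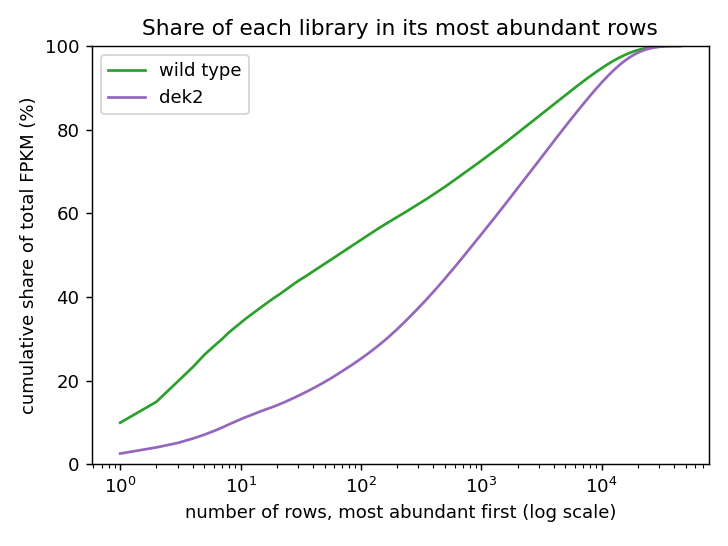
Cumulative share of total FPKM (y axis, percent) against the number of rows taken in order of abundance (x axis, log scale) for the wild-type and the dek2 library. The wild-type curve starts higher: 10 rows hold 33.8% of wild type and 10.8% of dek2.

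The most abundant locus of wild type lay in a group of neighbouring loci on chromosome 7 whose region is given with the other groups. It had 113227 FPKM in wild type and 803 FPKM in dek2, a log2 ratio of -7.72. The next in order, on chromosome 2, had 56939 FPKM in wild type and 2511 FPKM in dek2, a log2 ratio of -5.09. The smallest difference among the 10 was at a locus on chromosome 6 with 33818 FPKM in wild type and 4238 FPKM in dek2, a log2 ratio of -3.58. Another of the 10, on chromosome 7 from 120206896 to 120208211, had 12296 FPKM in wild type and 50.1 FPKM in dek2. Close to it, the coordinate from 120233939 to 120236057 summed to 11304.5 FPKM in dek2 and had no value in wild type. Whether signal was assigned to different neighbours in the 2 libraries was not tested, so the lower value at the first locus is uncertain.

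Part of the strongly lower rows were grouped on the chromosomes. The grouping was noticed in the data and the definition of a cluster was set after that. At 50 FPKM or more in wild type and a span of 300 bp or more, 71 rows were at least 32-fold lower in dek2 or, for 11 of them, listed at the placeholder there, and 39 of them fell into 5 clusters of neighbouring loci, while 32 lay outside. Of the 39 clustered rows, 38 had a value in dek2. Random draws of 71 rows from the 2117 rows at 50 FPKM or more in wild type and 300 bp or more in span put at most 9 rows into such clusters in 1000 draws, with a median of 0. The draws were not matched on the level of the clustered rows and did not keep abundant neighbours together. They therefore describe the grouping and say nothing of its source. The 39 clustered rows, at 30 distinct coordinates, held 29.6% of the wild-type FPKM and 0.148% of the dek2 FPKM. Their median log2 ratio was -8.37, and their ratios lay between -10.05 and -5.35. Of the 10 most abundant wild-type rows, 6 belonged to these clusters.

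The cluster with the highest summed level lay on chromosome 7 between 18755935 and 18955697. Its 8 loci summed to 155329 FPKM in wild type and 1071 FPKM in dek2, 218-fold lower after scaling. A cluster on chromosome 4 between 5083078 and 5595805 held 20 rows at 13 coordinates. It summed to 124953 FPKM in wild type and 364 FPKM in dek2, 516-fold lower. A second interval on chromosome 4, from 29951760 to 30091004, held 5 rows at 3 coordinates and was 727-fold lower, with 50015 FPKM in wild type and 103 FPKM in dek2. The cluster on chromosome 1 between 161790709 and 162097052 had 3 rows, with 6007 FPKM in wild type and 37.8 FPKM in dek2, 239-fold lower. The smallest, on chromosome 6 between 31567088 and 31650417, had 3 rows, with 624 FPKM in wild type and 13.1 FPKM in dek2, 71.3-fold lower. Inside the 5 intervals, 21 other loci at 1 FPKM or more had a median log2 ratio of -0.82, with 9 of them at least 2-fold lower and 0 higher. Most of these lay in the longer chromosome 4 interval, where, counted by row and not by locus, 19 other rows had a median of -0.82. In the other intervals, 2 other rows had a median of -4.84 on chromosome 7 and 1 other row had -2.46 on chromosome 1. In the second chromosome 4 interval 2 other rows had a median of 0.41. Neighbouring members of such clusters can share reads where their sequences are alike, so the values of single members are uncertain, and the sums cover only rows selected as lower. The sum over the clustered rows was 319-fold lower in dek2 with the scaling and 212-fold without it. Over all 82 rows in the 5 intervals, the sum was 337343 FPKM in wild type and 1946 FPKM in dek2, 260-fold lower with the scaling and 173-fold without it.

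**Figure D2:**
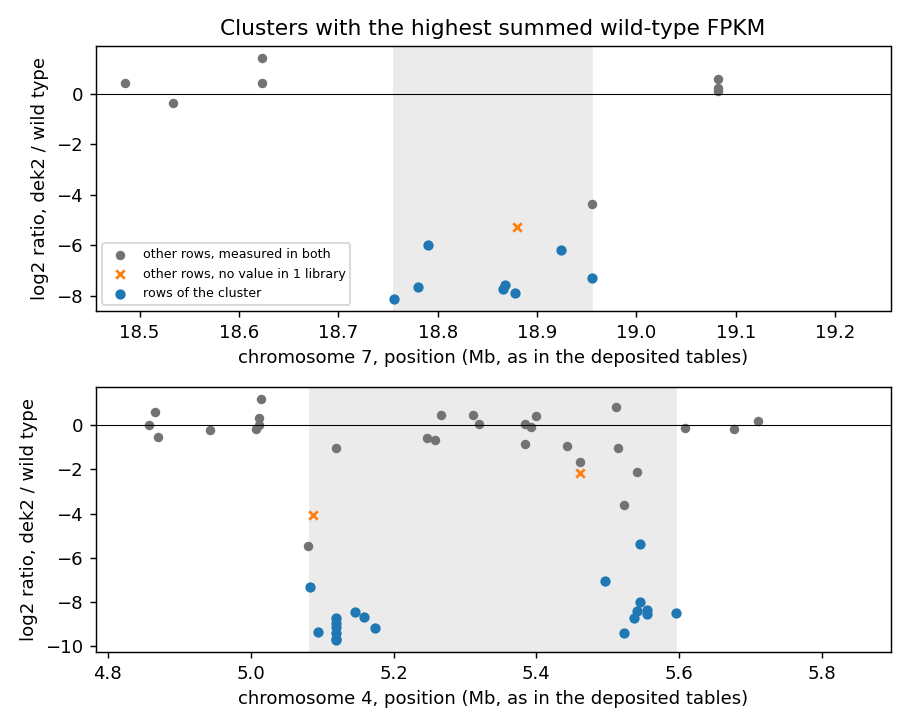
Log2 ratio of dek2 to wild type (y axis) by position in Mb (x axis) around the chromosome 7 and chromosome 4 clusters with the highest wild-type FPKM; each point is 1 row at 1 FPKM or more in a library and the grey band is the cluster. Rows of the clusters lie at -5.39 or below on chromosome 4 and -5.98 or below on chromosome 7, and other rows inside the chromosome 4 band range from above 0 to below -1.

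Over all rows, the numbers higher and lower depended on the scaling between the libraries. Of 28476 rows at 1 FPKM or more in a library, 3759 (13.2%) were at least 2-fold higher in dek2 and 3418 (12.0%) were at least 2-fold lower after the median shift was removed. The remaining rows differed by less than 2-fold, and the middle 50% of all log2 ratios lay between -0.51 and 0.62. Of the counted rows, 52.4% were higher in dek2, against 80.1% on the deposited values without scaling between libraries and 49.5% when the libraries were set equal without the 100 most abundant rows of each, which turns the direction. Among the higher rows 744 had no value in wild type, and among the lower rows 540 had no value in dek2, so that 3015 higher and 2878 lower rows had a value in both. Large differences were about as frequent in both directions over all counted rows, with 116 rows at least 32-fold lower and 108 at least 32-fold higher, and 338 and 336 at 8-fold. With a span of 300 bp or more and a value in both libraries, 62 rows were at least 32-fold lower and 17 at least 32-fold higher, and at 8-fold the numbers were 192 and 104. Of the 47 rows at least 32-fold higher at 50 FPKM or more in dek2 and 300 bp or more in span, 17 had a value in wild type, so this condition removes many higher rows.

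**Figure D3:**
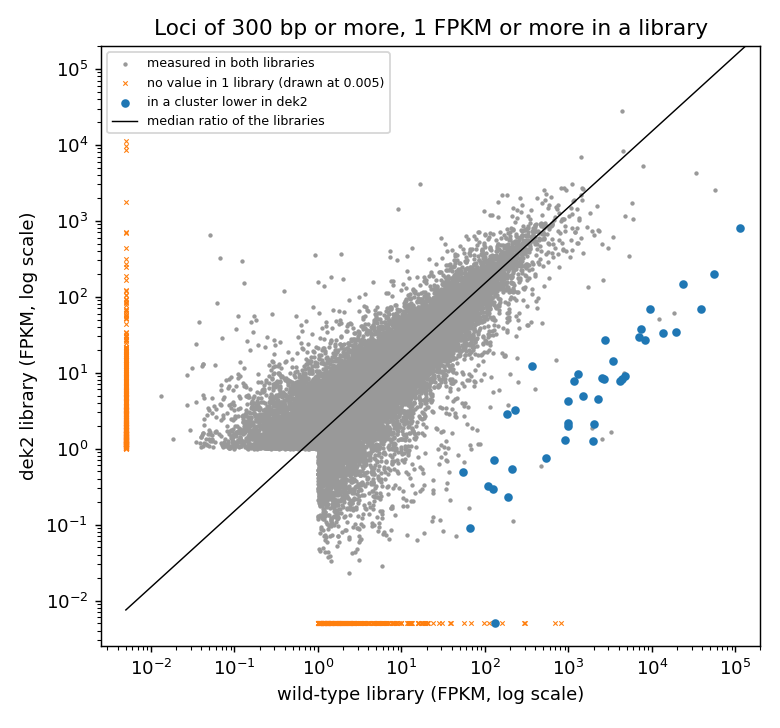
FPKM in the wild-type library (x axis) and the dek2 library (y axis), both on log scales, for rows with a span of 300 bp or more and 1 FPKM or more in a library. Blue points are rows of the 5 clusters, crosses are rows with no value in 1 library drawn at 0.005, and the line marks the median ratio of the libraries; the blue points lie far below the line, with a median log2 ratio of -8.37.

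The most abundant rows were mostly lower in dek2, while the less abundant rows went both ways. At a mean of 1000 FPKM or more, 47 of 81 rows (58.0%) were at least 2-fold lower, 15 were higher, and the median log2 ratio was -2.18. Among those of 300 bp or more with a value in both libraries, 42 of 61 rows (68.9%) were lower and 7 were higher, with a median of -3.06. Between 100 and 1000 FPKM, 187 of all 1044 rows were higher and 159 were lower, with a median of 0.19. Between 10 and 100 FPKM, 1102 of 8876 rows were higher and 945 lower, and between 1 and 10 FPKM, 2085 of 15088 rows were higher and 1912 lower, with a median of 0.04 in both classes. These last 2 medians were -0.01 and -0.0023 when the libraries were set equal without the 100 most abundant rows of each, so no direction is read from them.

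The lowest ratios among rows with a coordinate of their own, a span of 300 bp or more, 10 FPKM or more in a library and a value in both were at 2 loci on chromosome 6. The locus from 39091666 to 39092487 had 3267 FPKM in wild type and 1.63 FPKM in dek2, a log2 ratio of -10.61. The locus from 39087614 to 39088302 had 2527 FPKM in wild type and 1.32 FPKM in dek2, a log2 ratio of -10.39. The highest ratios among the same rows were at a locus on chromosome 10 from 46063646 to 46066005, with 0.0507 FPKM in wild type and 647 FPKM in dek2 (log2 ratio 8.68), and at a locus on chromosome 1 from 11298551 to 11299266, with 0.122 and 292 FPKM (log2 ratio 7.44). With a pseudocount of 0.1 these 4 log2 ratios were -11.43, -11.33, 11.48 and 9.77. The 47 rows at least 32-fold higher in dek2 at 50 FPKM or more formed 0 clusters by the definition used for the lower rows.

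Rows of the mitochondrial and plastid genomes were at the low end of both libraries. The 38 mitochondrial rows summed to 14.6 FPKM in dek2 and 13.5 FPKM in wild type, and a value was given for 32 of them in dek2 and for 25 in wild type. Only 6 reached 1 FPKM in a library. Of these, a row with a span of 378 bp was lower in dek2, with 4.45 FPKM in wild type and 0.459 FPKM in dek2 (log2 ratio -2.06). Rows with spans of 258 bp and 840 bp had 2.83 and 1.12 FPKM in dek2 and were listed at the placeholder in wild type. The 3 remaining rows, measured in both, differed by less than 2-fold on the scale used, where the pseudocount of 1 FPKM weighs heavily at such levels. They had 2.61, 0.312 and 1.94 FPKM in dek2 against 0.725, 1.08 and 1.48 FPKM in wild type (log2 ratios 0.67, -0.78 and -0.11). The 6 plastid rows had values in dek2 only, the highest at 0.338 FPKM. The number of fragments behind these low values is unknown, so no difference between the libraries is read from them, and FPKM per row says nothing of splicing.

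The differences of 2-fold or more were found on all 10 chromosomes in like shares. Among rows of 300 bp or more, the share at least 2-fold higher in dek2 lay between 11.3% on chromosome 4 and 13.5% on chromosome 3. The share at least 2-fold lower lay between 10.2% on chromosome 5 and 12.1% on chromosome 4. The chromosome medians of the log2 ratio lay between 0.03 and 0.12. In 201 windows of 10 Mb with at least 30 loci, the median lay between -0.27 and 0.40.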

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

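The counts depended on the scaling and on the fold threshold. On the deposited values, 8362 rows were at least 2-fold higher in dek2 and 2075 lower, against 3759 and 3418 after the median shift of 0.59 was removed. The construction explains this, since it moves rows up by as much as that shift (less at low values, through the pseudocount). The trimmed mean gave the same shift (0.59), and setting the rest equal after leaving out the 100 most abundant rows of each library gave 0.64, with 3523 higher and 3595 lower. A pseudocount of 0.1 raised the higher rows to 5796, a filter of 5 FPKM lowered the lower rows to 2199, and a 3-fold threshold left 1552 higher and 1427 lower. The direction of each of these changes follows from its construction, since a smaller pseudocount moves log2 ratios further from 0. All other alternatives run for these 2 counts stayed within 1.5 times. Added after the data were seen were both other scalings for single loci and medians, the medians of rows of 300 bp or more measured in both, leaving out the 100 most abundant rows, rows with their own coordinate, coordinates summed, spans of 300 bp or more and rows with a value in both libraries, and the 3 alternatives for the shares of the 10 most abundant rows, which moved by less than 5 percentage points. For single loci, cluster and class medians, 4 of 60 alternatives reversed a sign, all when the 100 most abundant rows were left out: the medians at 10 to 100 FPKM (-0.01 over all rows and over those of 300 bp or more measured in both) and at 1 to 10 FPKM (-0.0023 and -0.01), which lie near 0 so that a shift of 0.64 in place of 0.59 turns them. On the deposited values they moved by up to the shift of 0.59 itself, and 4 single loci moved further, each with a pseudocount of 0.1. Not run for lack of gene names were the rescaling without zein genes, the gene list medians and the dek2 transcript; not run for lack of counts was the counting interval. Leaving out replicates was not possible with n = 1. Depth limits what is said about rows near 1 FPKM, about short loci and about the organellar rows.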

Other observations

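Every test in this part was chosen after the result it bears on had been seen. With spans of 300 bp or more on chromosomes 1 to 10, 681 rows had 1 FPKM or more in dek2 and no value in wild type, and 346 rows had the reverse. Neighbouring loci had slightly alike ratios also without the clustered rows: over 24723 loci the rank correlation between neighbours was 0.0344, against a highest value of 0.0185 in 1000 shuffles. This is a correlation across loci within 1 pair of libraries, and loci are not replicates. Among loci at 1000 FPKM or more in dek2 with a coordinate of their own, a span of 300 bp or more and a value in both libraries, the highest log2 ratios were 6.81 at a locus on chromosome 9 (16.9 FPKM in wild type, 3018 FPKM in dek2) and 6.54 at a locus on chromosome 3 (9.08 and 1410 FPKM).

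The clustered loci were far lower in dek2. Reads moved between copies inside the intervals would leave the sum of every row there within 2-fold, but that sum was 260-fold lower after scaling. Wild-type RNA carried over is argued against as the whole source of what is left. Summed clusters kept 0.207% to 2.11% of their wild-type level, while the lowest rows at 1000 FPKM or more in wild type kept 0.0499% and 0.0524%. Those rows are the neighbouring chromosome 6 loci from 39091666 and 39087614, so this bound rests on a single region. Mutant-background sequence unlike the reference, which reads would then fail to match, could not be decided. Within 1 Mb of the clusters, 136 other loci had a median log2 ratio of -0.07 (95% bootstrap interval over loci -0.11 to 0.04). No broad loss of reads was therefore seen around the clusters. A background that differs only in the clustered loci would give the same value, so this does not argue against it. Inside the intervals it cannot be told apart from a lower expression either. The 21 other loci there had a median of -0.82 (-1.66 to 0.05), an interval that includes the bound of -1. This value comes mostly from 1 interval on chromosome 4. The few rows in the others had a median of -4.84 on chromosome 7, -2.46 on chromosome 1 (1 row) and 0.41 in the second chromosome 4 interval. Open and untested are reads moved to copies elsewhere, sequence differences within the copies themselves, another share of tissues in the dek2 sample, and the genotype. Maize endosperm is known to have tandem families of abundant storage-protein genes, and whether these loci belong to them was not tested, because the deposited tables pair no locus with a gene.

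The median locus was 0.59 higher (log2) in dek2 on the deposited scale, while the FPKM totals differed by -0.09. The FPKM worth of 1 fragment differed by -0.08 (log2) in dek2 relative to wild type, the opposite direction. This argues against a larger FPKM worth per fragment in dek2 as the source. FPKM divides depth out, so this value does not test a difference in depth itself. A candidate explanation is that the abundant clustered loci take up the wild-type library. Without them the FPKM totals differed by 0.42, short of 0.59 by more than the 0.15 that had been allowed. This leaves out the clustered rows only, and other abundant wild-type rows stay in, such as that of 56939 FPKM on chromosome 2. Without the 100 most abundant rows of each library the rest differed by 0.64, so the shortfall does not speak against abundant rows in general. Their effect cannot be told apart from a higher level of many loci in dek2, since FPKM carries no outside standard.

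Some rows abundant in dek2 were listed at the placeholder in wild type, and 5 explanations were tried for them. The first tests took the 4 rows at 1000 FPKM or more: counted by row, 5.80% of 69 were at the placeholder against 0.783% of 1532 rows at 100 to 1000 FPKM, and counting coordinates with no row measured in wild type it was 3.03% (2 of 66, exact 95% interval 0.369% to 10.5%) against 0.0687% (1 of 1455), which both go with estimates not made at very deep loci, but 10 wild-type rows had values above the highest of these and in the reverse direction 0 of 75 rows were at the placeholder in dek2 against 0.889% of 900, so this cannot be told apart from other sources. Of the other early tests, the one of a transcript absent from wild type (0 rows with a measured value under 1 FPKM) decided nothing, and that of short loci (smallest span 568 bp) was void, because only spans of 300 bp or more were taken. The rows were then widened to 100 FPKM or more, and shared coordinates were tested after it had been seen that 14 of 16 rows shared one: 86.7% of their 15 coordinates held several rows (exact 95% interval 59.5% to 98.3%) against 23.4% of 1508 measured coordinates, but in the reverse direction it was 37.5% of 8 (8.52% to 75.5%) against 26.4% of 936, so that an estimate not made for some rows of such coordinates cannot be told apart from other sources. Fragments given to another row of the coordinate are argued against as the whole source by 12 of 13 coordinates still at least 2-fold higher in dek2 when summed. The chromosome 7 coordinate from 120233939 was certain to count, since none of its rows had a value in wild type. It lies close to the locus from 120206896, which had 12296 FPKM in wild type and 50.1 FPKM in dek2. Fragments given to a neighbouring coordinate were not tested. A part moved between rows is not excluded. Nor is a different order of the rows of a coordinate in the 2 libraries, which would pair them wrongly but leave the sums unchanged. Absence from wild type through the genotype stays open for single rows, but not for every coordinate. Wild-type sums reached 148 FPKM at 1 coordinate on chromosome 1 and 115 FPKM at 1 on chromosome 3.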
